A study of Homo sapiens with 79 samples.

How the data were processed

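Platelet total RNA in 79 samples of 3 groups was measured, 1 array per sample: 27 with essential thrombocythemia (ET, a clonal blood disease with a raised platelet count), 22 with reactive thrombocytosis (RT, a raised count secondary to another condition) and 30 healthy controls. Per the labels' protocols, platelet RNA came from platelet-rich plasma, leukocytes were separated by density gradient and were rare in the plasma, RNA was extracted with Trizol, and miRNA ends were labelled with Cy3 for an Agilent human miRNA array in 1 colour. The groups are those of the labels' phenotype field. The arrays lay on 11 slides, read from the array descriptions in the labels. 8 slides held arrays of more than 1 group (56 arrays), and 1 slide each held only healthy, only ET and only RT arrays.

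Per the file headers, each scanner file holds spot intensity from Agilent Feature Extraction after background subtraction, with no scaling between arrays (gProcessedSignal, equal to the background-subtracted signal in these files), and the total intensity that software sums per miRNA. The releases of that software differed between slides, and 38 arrays used newer names for some of the same probes. 1 human miRNA was renamed between them, and the older name was kept. The deposited value table is log2, with 392 miRNAs and an equal median in every column. Per the submitters' processing notes, RMA, limma and R 2.11 were used, and the order of the steps is not given in the sources used here. The array holds 2689 probes for 851 human and 88 viral miRNAs, with 4 to 16 spots per probe and 1 to 4 probes per miRNA. Names are those of the array, which predate current arm names, and the species prefix hsa- is left out of the text. No genome positions were used.

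The values compared here were computed from the scanner files. Spots not marked as outliers were averaged per probe. Each array was scaled so that its 75th percentile over the 350 probes well above background on all arrays was equal across arrays, signals under a floor of 5.26 (log2 2.39), the median over arrays of the lowest signal well above background, were raised to it, and the log2 values of a miRNA's probes were averaged. A human miRNA was tested if it was well above background, by the software's own mark on at least 0.5 of the spots of 1 or more of its probes, on at least 0.5 of the arrays of at least 1 group. This left 390 miRNAs, of which 198 were well above background on all 79 arrays. All 79 arrays entered 1 limma model (limma 3.58.1, R 4.3.3) with the group and the slide as fixed terms, so that group differences came from within the mixed slides, and moderated two-sided tests were adjusted by the Benjamini-Hochberg method within each comparison. A miRNA was called at an adjusted p under 0.05 with no minimum fold. The limma fit shares 1 estimate of the spread over the 3 groups.

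The signal on each array was summarised by that 75th percentile and by the number of human miRNAs well above background. The number of arrays limits the precision. Tested on simulated data for 390 miRNAs, of which 60 were changed by known amounts, the fit recovered 48.8%, 86.2% and 99% of log2 changes of 0.5, 1 and 2 between ET and healthy, 49.5%, 83.5% and 99.2% between RT and healthy, and 42.8%, 84% and 99.2% between ET and RT.

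The fold of a miRNA that was not well above background on every array of a group is given as a bound: the brighter group's mean against the dimmer group's mean after each of its values was raised to the lowest signal well above background on its array. The bound takes no account of the slide, of sampling error or of the other scalings. Where no value was raised it equals the ratio of the group means. The fitted log2 differences of such miRNAs depend on the floor and are no bounds. The miRNAs named in a comparison were fixed by a rule before the data were examined: up to 12 called miRNAs with the largest positive and up to 12 with the largest negative log2 difference, without those whose direction turned when the slide was left out, up to 4 members with the smallest p of each list described, and a fixed panel of miRNAs known from platelets and myeloproliferative disease. Others are named only where the text says that they were chosen after their values were seen.

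21 lists of miRNA families, clusters and markers of blood cells and other tissues, fixed in the same way, were tested in the 3 comparisons with camera (preset correlation 0.01), adjusted over 63 tests, and again with an estimated correlation and with fry. The overlap of calls against the same healthy arrays was set beside simulated unchanged groups and beside 20 splits of the healthy arrays. Means over an array were compared by permuting labels within slides, with 100000 resamples (two-sided). List means were permuted only for lists that had passed camera in these data. Their adjustment covers 3 comparisons and not the choice among 21 lists. The alternatives tried were other scalings (75th percentile over all probes, quantile normalization, RMA, normexp background correction, the software's total signal, the brightest probe, the deposited table), other floors and filters, other block terms, array weights, other forms of the limma test, a stricter threshold, and leaving out each slide. The normexp correction used the median spot and background signal, because the files hold no mean spot signal, and an offset of 50. The RMA alternative started from the same corrected signals. Array brightness as a covariate, and leaving out 4 dim arrays (over 3 median absolute deviations under the median log2 75th percentile), were added after the data were seen. Of these 4 dim arrays, 3 were healthy and 1 was ET. No array was left out of the main comparisons. Figures were drawn with matplotlib 3.10.9.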

Results

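Platelet miRNAs were measured on 79 arrays from 30 healthy controls, 27 samples of ET and 22 of RT. The 75th percentile of the probes detected throughout ranged from 498 to 16328 intensity units per array, with a median of 4664. Between 259 and 451 human miRNAs were well above background per array, with a mean of 362 ± 38.3 in healthy (SD, n = 30), 384 ± 32.3 in ET (SD, n = 27) and 374 ± 18.8 in RT (SD, n = 22). Within the mixed slides ET exceeded healthy by 19.2 miRNAs (permutation p = 0.0658, adjusted over 3 comparisons 0.197), RT exceeded healthy by 11.3 (permutation p = 0.395) and ET exceeded RT by 7.93 (permutation p = 0.335). Array brightness differed by log2 0.06, 0.10 and -0.05 in the same comparisons (permutation p = 0.858, 0.795 and 0.862).

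The comparison of ET with healthy platelets addresses which miRNAs differ in platelets of the clonal disease. 3 sets of related miRNAs stood far above healthy platelets. miR-490-3p was at least 8.66-fold higher, with a mean log2 signal of 6.07 ± 1.78 (SD, n = 27) in ET and 2.61 ± 0.66 (SD, n = 30) in healthy, and was well above background on 25 of 27 ET and 5 of 30 healthy arrays. miR-34a, which the tumour suppressor p53 induces, was 5.66-fold higher by its group means (8.85 ± 0.98 against 6.35 ± 0.75). miR-34b*, from a related hairpin, was at least 3.95-fold higher. Probes for related sequences can share signal, and whether miR-34b* rose apart from miR-34a was not tested. Both arms of miR-9, a miRNA abundant in neural tissue, were higher as well, by at least 3.41-fold for miR-9 and 4.19-fold for miR-9*. These folds apply to the main scaling only. Together with miR-490-5p, these miRNAs had a median log2 difference of 2.62 there, 0.795 under RMA and 0.832 under normexp.

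In limma, miR-490-3p passed the test (adjusted p = 1.41e-11), and its fitted difference is set in part by the floor, at which most healthy arrays lay. The fitted log2 differences of the others, each with its SE and dependent on the floor where healthy arrays were at background, were 2.76 ± 0.25 for miR-34a (adjusted p = 7.85e-14), 2.69 ± 0.34 for miR-9*, 2.55 ± 0.25 for miR-34b*, 2.15 ± 0.28 for miR-9 and 1.92 ± 0.25 for miR-490-5p. Each of the 6 was higher in ET on 8 of the 8 slides that held both groups and under 7 of 7 other scalings. The plot of array values shows that a few ET arrays lay at the floor for miR-490-3p and that most lay above the healthy arrays for miR-34a.

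**Figure D1:**
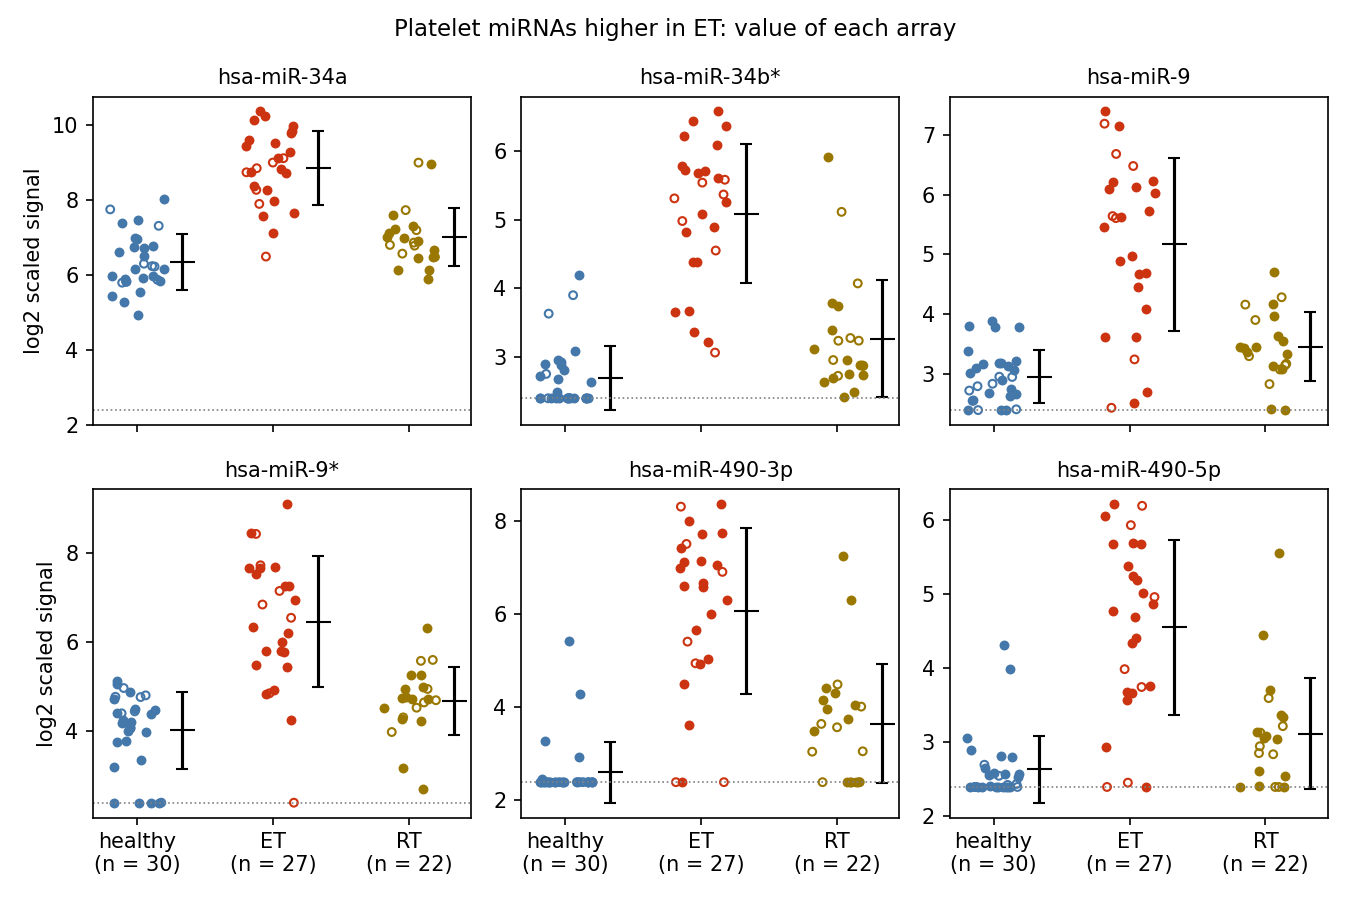
log2 scaled signal of 6 miRNAs on each array in 3 groups (healthy n = 30, ET n = 27, RT n = 22). Points are arrays, open points lie on single-group slides, bars give the mean ± SD and the dotted line is the floor at 2.39; for miR-490-3p the ET mean is 6.07 against 2.61 in healthy and 3.65 in RT.

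Among brighter miRNAs, miR-424 and miR-503, which share 1 primary transcript, were higher in ET by log2 1.68 ± 0.33 (SE, 3.20-fold, adjusted p = 4.50e-05) and 1.20 ± 0.29. In the miR-15/16 family, which has the seed of miR-424, 3 of 6 measured members rose (3 also adjusted over the list alone): miR-424, miR-497 by 1.07 ± 0.23 and miR-195 by 0.91 ± 0.19. The family median was 0.49 (camera adjusted p = 0.216). All 3 measured members of the miR-29 family, regulators of collagen mRNAs, rose (3 of 3 adjusted over the list alone): miR-29b by 1.28 ± 0.32, miR-29a by 1.18 ± 0.20 and miR-29c by 0.55 ± 0.18. As a list the family did not pass the test (median 1.18, camera adjusted p = 0.0870). miR-148a rose by 1.22 ± 0.24 (adjusted p = 6.28e-05). miR-886-3p, since reclassified as a fragment of a vault RNA, rose by 1.48 ± 0.24, and miR-136* by 1.27 ± 0.43 (adjusted p = 0.0195).

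The miR-181 family, known from lymphocyte development, was lower in ET as a list, with a median log2 difference of -0.83 (camera adjusted p = 0.0178; adjusted p = 0.575 with an estimated correlation). 3 of its 4 members fell, and all 4 when adjusted over the list alone: miR-181c by 0.90 ± 0.20 on the log2 scale, miR-181a by 0.84 ± 0.25 and miR-181d by 0.83 ± 0.19, while miR-181b had a difference of -0.44 ± 0.19 (adjusted p = 0.0642). The difference of the family's mean was -0.71 within the mixed slides (permutation p = 0.00077, adjusted over 3 comparisons 0.00231). The adjustment leaves out the choice of this list by camera in the same data. Camera at its preset correlation passed at least 3 lists in 94 of 100 regroupings of the arrays within slides, the real one included. Its adjusted p by itself is thus no evidence of a shift, here and for the lists below. From the HOX gene clusters, miR-196b fell by 0.75 ± 0.11 (adjusted p = 2.29e-07) and miR-10a by 0.64 ± 0.22, and miR-10b had a difference of -0.10 ± 0.10 (list median -0.64, camera adjusted p = 0.0783, and 0.0209 without the slide block; 2 of 3 members fell over all miRNAs and over the list alone). Other miRNAs that fell were miR-551b by 1.00 ± 0.31, miR-1301 by 0.92 ± 0.20, miR-181c* by 0.89 ± 0.22, miR-330-3p by 0.80 ± 0.14, miR-328 by 0.76 ± 0.16, miR-99b by 0.74 ± 0.26, miR-423-5p by 0.72 ± 0.23 and let-7d* by 0.70 ± 0.19. All named decreases kept their direction under 7 of 7 other scalings.

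Markers of other blood cells moved unevenly in ET. Of 8 lymphocyte miRNAs, 3 fell and 1 rose (median -0.53, camera adjusted p = 0.196; 4 and 1 over the list alone), including miR-181a and miR-342-3p, which fell by 0.64 ± 0.24. miR-150, the most lymphocyte-restricted of them, had a difference of -0.76 ± 0.58 (adjusted p = 0.312). Among 6 erythroid miRNAs, miR-363 rose by 0.94 ± 0.20 and miR-486-3p by 0.46 ± 0.12 (called under 2 of 7 other scalings), while miR-451 had a difference of -0.31 ± 0.41. Of 8 monocyte and granulocyte miRNAs, 3 rose (3 over the list alone; median 0.26, -0.00 to 0.32 over the other scalings, camera adjusted p = 0.430): miR-424, miR-146b-5p by 0.51 ± 0.19 and miR-223* by 0.36 ± 0.14 (called under 2 and 0 of 7 other scalings). Of the 26 platelet-abundant miRNAs, 2 rose and 2 fell (1 and 2 over the list alone), with a median of 0.06 and a mean of 0.02, while the list test, which compares the list with all other miRNAs, pointed down (camera adjusted p = 0.351). The median ran from -0.22 to 0.07 over the other scalings. miR-126, found in platelets and endothelium, rose by 0.39 ± 0.15, miR-142-3p rose by 0.64 ± 0.19 and miR-30c fell by 0.32 ± 0.08. miR-223, miR-145, miR-146a, miR-155 and miR-28-5p, all of the fixed panel, had differences of 0.25 ± 0.12, -0.11 ± 0.23, -0.28 ± 0.13, -0.01 ± 0.15 and -0.09 ± 0.14 and did not pass the test.

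Other lists did not pass the list test in ET. The medians were -0.11 for the myeloproliferative list, -0.10 for megakaryocyte differentiation, -0.17 for the miR-30 family, -0.20 for the miR-23/27/24 clusters, -0.50 for muscle and 0.51 for liver. In the liver list 2 of 3 members rose (2 over the list alone): miR-215 by 0.66 ± 0.20 and miR-192 by 0.51 ± 0.20. For 6 lists the sign of the median turned under another scaling: endothelial (0.06), epithelial (0.25), inflammation-responsive (0.19), the let-7 family (0.08), the cluster of miR-17 with its paralogs (0.08) and the miR-183 cluster (0.05). Among their members, miR-18b rose by 0.39 ± 0.09 (called under 0 of 7 other scalings), miR-182 fell by 0.64 ± 0.14, miR-190 fell by 0.38 ± 0.10 and miR-93 fell by 0.24 ± 0.07. miR-429 was higher by 0.31 ± 0.11 (adjusted p = 0.0258), with a difference of -0.00342, -0.0110 and -0.0823 under the percentile over all probes, quantile normalization and normexp.

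In total 125 of 390 miRNAs were called between ET and healthy, 79 higher and 46 lower (63.2% higher), and 162 had an unadjusted p under 0.05. The median of all 390 differences was 0.09, and the median size of a called difference was 0.58. The split depended on the scaling: it was 29 higher and 94 lower with the percentile over all probes, 40 and 63 with quantile normalization, 42 and 70 with RMA, 34 and 68 in the deposited table and 68 and 61 with the software's total signal. The median of all differences shifted by -0.19, -0.16 and -0.12 with the percentile over all probes, normexp and the deposited table, and 106 of the 125 kept their sign under all scalings. Without slide 9 the count was 79. Without the slide block miR-30c, miR-93, miR-99b, miR-126, miR-142-3p, miR-223* and miR-342-3p were not called, and kept their direction.

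The comparison of RT with healthy platelets addresses what accompanies a raised platelet count without the clonal disease. miR-424 was again higher, by log2 1.37 ± 0.36 (SE, 2.58-fold, adjusted p = 0.00740), as were miR-363, of an erythroid and proliferation-linked cluster, by 1.14 ± 0.22 (2.21-fold, adjusted p = 0.00109) and miR-148a by 1.01 ± 0.27. Of the 44 members of the list for the imprinted DLK1-DIO3 locus, a large maternally expressed cluster, 5 were called lower: miR-485-3p fell by 1.39 ± 0.41 on the log2 scale, miR-382 by 1.28 ± 0.41, miR-543 by 1.19 ± 0.39, miR-134 by 1.12 ± 0.39 and miR-433 by 1.08 ± 0.37. miR-490-3p was higher than in healthy platelets in RT too, by at least 1.62-fold (adjusted p = 0.0438; called under 3 of 7 other scalings), and was well above background on 16 of 22 RT arrays.

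The DLK1-DIO3 list had a median log2 difference of -0.65 in RT (camera adjusted p = 2.30e-08; adjusted p = 0.575 with an estimated correlation and 0.178 with fry). When adjusted over the list alone 5 of the 44 members were lower as well, and the mean over the members differed by -0.63 ± 0.35 (SE, 95% interval -1.33 to 0.06). Within the mixed slides that mean differed by -0.57 (permutation p = 0.131, adjusted over 3 comparisons 0.131). The size depended on the scaling, with a median of -0.33 under RMA and -0.17 under normexp. The 5 calls became 0 without slide 4 or 8 (limma, 5 and 8 at an unadjusted p under 0.05), 1 without slide 7, 2 without slide 5, 9 or 10 and 3 without slide 3. The miR-181 family did not pass the list test in RT, and 2 of its 4 members were lower over all miRNAs and over the list alone: miR-181d fell by 0.85 ± 0.21 and miR-181c by 0.65 ± 0.22 (list median -0.56, camera adjusted p = 0.0625, and 0.0274 without the slide block). The difference of the family's mean was -0.65 within the mixed slides (permutation p = 0.00354, adjusted over 3 comparisons 0.00531, without the choice of the list). miR-181c* fell by 0.78 ± 0.24, miR-328 by 0.78 ± 0.18, miR-423-5p by 0.72 ± 0.25, miR-1301 by 0.69 ± 0.22 and let-7d* by 0.62 ± 0.21.

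Among the increases in RT were miR-193a-3p by 1.15 ± 0.25, miR-545 by 0.95 ± 0.33, miR-199b-5p by 0.93 ± 0.24, miR-542-5p by 0.91 ± 0.30, miR-362-3p by 0.88 ± 0.27, miR-219-5p by 0.87 ± 0.25 and miR-142-3p, a miRNA of all blood lineages, by 0.88 ± 0.21. Of 3 liver miRNAs, 2 rose (2 over the list alone): miR-215 by 0.84 ± 0.22 and miR-192 by 0.83 ± 0.22, while miR-194 had a difference of 0.15 ± 0.11 (list median 0.83, camera adjusted p = 0.0842). Of 8 monocyte and granulocyte miRNAs, miR-424 and miR-338-3p rose, the latter by 0.87 ± 0.23, and miR-132 fell by 0.33 ± 0.11 (list median 0.26, camera adjusted p = 0.351; 3 higher and 1 lower over the list alone). In the erythroid list, miR-363 passed the test, and miR-144 and miR-451 had differences of 1.12 ± 0.50 and 0.66 ± 0.46 (list median 0.58, camera adjusted p = 0.249). Of the platelet-abundant miRNAs, miR-142-3p and miR-21 rose, the latter by 0.36 ± 0.11, and miR-26a fell by 0.29 ± 0.08 (median of 26 members 0.13, camera adjusted p = 0.556). In the fixed panel, miR-34a had a difference of 0.59 ± 0.28 (adjusted p = 0.142), miR-490-5p of 0.57 ± 0.28, miR-223 of 0.36 ± 0.14 and miR-126 of 0.28 ± 0.16, and none of the 4 passed the test. Without the slide block miR-34a (0.66, adjusted p = 0.0297) and miR-223 (0.41, adjusted p = 0.0303) passed.

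Without the slide block miR-132 and miR-545 were not called, and miR-21, miR-132 and miR-181c were called under 1, 1 and 2 of 7 other scalings.

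In total 57 of 390 miRNAs were called between RT and healthy, 34 higher and 23 lower (59.6% higher), with 116 at an unadjusted p under 0.05. The split was 8 higher and 24 lower with the percentile over all probes, 17 and 26 with quantile normalization, 17 and 23 with RMA, 15 and 17 in the deposited table, 29 and 43 with the total signal and 5 and 0 with normexp. Without slide 3, 5, 7, 8, 9 or 11 the count was 31, 30, 19, 29, 20 or 21.

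40 miRNAs were called in the same direction in ET and in RT against healthy, 25 higher and 15 lower, and 0 were called in opposite directions (limma; 76 were shared in direction at unadjusted p under 0.05). miR-424, miR-363, miR-148a, miR-142-3p, miR-545 and miR-490-3p were among those higher in both, and miR-181c, miR-181d, miR-328, miR-423-5p, miR-1301 and let-7d* among those lower in both. Both comparisons use the same healthy arrays. Unchanged groups simulated against those arrays shared a median of 0 and at most 0 calls. Groups without change give few calls of any kind, so this count is no reference for the 40. Independent lists of these sizes would share 6.89 higher and 2.71 lower. The correlation of the differences over miRNAs was 0.395 against 0.377 simulated, and the covariance 0.0956 against 0.0226. With separate healthy arrays for each comparison the shared count had a median of 14.5 over 20 splits (0 to 23), with a median correlation of 0.250 and covariance of 0.0680. Each comparison then used fewer healthy arrays and had fewer calls (medians of 77 for ET and 42.5 for RT). The lower shared count therefore cannot be credited to the separate healthy arrays alone. miRNAs are not independent replicates. Without slide 3, 5, 7, 8, 9 or 11 the shared count was 22, 23, 12, 23, 13 or 13.

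The direct comparison of ET with RT addresses what separates the clonal from the reactive form of a high platelet count. The miRNAs that stood highest in ET against healthy were also higher in ET than in RT: miR-490-3p by at least 5.07-fold (adjusted p = 7.90e-05), miR-34a by log2 2.16 ± 0.29 (SE, adjusted p = 4.12e-08), miR-34b* by 2.08 ± 0.28, miR-9* by 2.05 ± 0.38, miR-9 by 1.85 ± 0.32 and miR-490-5p by 1.35 ± 0.29. Each was higher in ET on 7 of the 7 slides that held both groups. Under normexp, only miR-34a of these was called between ET and RT. Members of the DLK1-DIO3 list made up 32 of the 67 calls, all higher in ET, among them miR-382 by 1.52 ± 0.43, miR-409-3p by 1.47 ± 0.44, miR-381 by 1.46 ± 0.47, miR-127-3p by 1.46 ± 0.48 and miR-376a by 1.45 ± 0.44. 3 miRNAs transcribed from 1 cluster were lower in ET than in RT: miR-125a-5p by a log2 difference of -1.24 ± 0.29, let-7e by -1.16 ± 0.33 and miR-99b by -0.92 ± 0.29. Without the slide block miR-99b had a difference of -0.51 and was not called (adjusted p = 0.167).

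**Figure D2:**
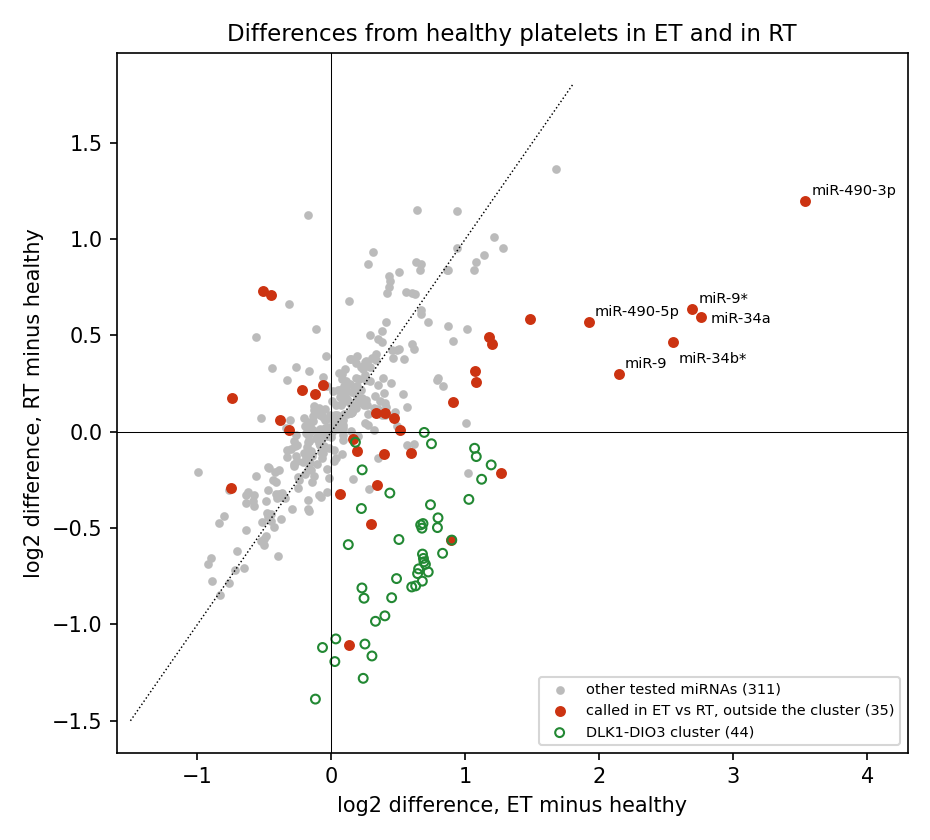
log2 difference from healthy in RT (vertical) against that in ET (horizontal) for 390 miRNAs, 1 point each, with the line of equal differences dotted. Filled red points are the 35 called between ET and RT outside the DLK1-DIO3 list and green circles its 44 members; miR-34a lies at 2.76 in ET and 0.59 in RT, and the cluster lies under the dotted line.

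The DLK1-DIO3 list had a median log2 difference of 1.28 between ET and RT (camera adjusted p = 1.65e-19; adjusted p = 0.575 with an estimated correlation of 0.737 between members, and 0.0119 with fry). 32 of 44 members were called, and 42 when adjusted over the list alone. The median was 0.50 under RMA and 0.44 under normexp, where limma called 0 members (13 at an unadjusted p under 0.05). Without slide 4, 7 or 10 the members called were 0, 6 or 1 in limma (37, 41 and 41 at an unadjusted p under 0.05), with medians of 1.11, 1.27 and 1.18. The mean over members was 1.18 ± 0.36 higher in ET (SE, 95% interval 0.47 to 1.90). The permutation test within mixed slides gave p = 0.01 (adjusted over 3 comparisons 0.03). The list was taken because it had passed camera, and the adjustment leaves this choice out. Group means of the cluster were 6.84 ± 1.00 in ET (SD, n = 27), 6.21 ± 0.85 in healthy (SD, n = 30) and 5.77 ± 1.11 in RT (SD, n = 22). Against healthy, ET differed by 0.55 ± 0.31 (SE, 95% interval -0.08 to 1.18). Within the mixed slides that difference was 0.51 (permutation p = 0.104, adjusted over 3 comparisons 0.131). 5 members were called there and 0 when adjusted over the list alone (limma; list median 0.65, camera adjusted p = 0.0870, and 0.0169 without the slide block). Those 5, of which miR-337-5p was chosen after its values were seen, were miR-299-5p, miR-337-5p, miR-376b, miR-380 and miR-411, and without slide 7, 9, 10 or 11 the count was 0, 0, 2 or 0 (limma, 6, 7, 7 and 7 at an unadjusted p under 0.05), and 10 without slide 8. 8 further calls between ET and RT were opposite arms of hairpins in the list by name, among them miR-136* by 1.48 ± 0.49 and miR-376a* by 1.45 ± 0.46.

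In the miR-29 family miR-29a was higher in ET by 0.68 ± 0.23 (1 of 3 members, also over the list alone; median 0.33, camera adjusted p = 0.418), and in the miR-15/16 family miR-497 by 0.75 ± 0.26 (called under 2 of 7 other scalings). let-7e* was lower in ET by a difference of -0.44 ± 0.09, miR-196b by -0.46 ± 0.13, miR-190 by -0.44 ± 0.12, miR-30c by -0.32 ± 0.09 (not called without the slide block), miR-140-5p by -0.32 ± 0.11 and miR-744* by -0.30 ± 0.11. miR-486-3p was higher in ET by 0.39 ± 0.14, but was called under 0 of 7 other scalings and not without the slide block (0.28, adjusted p = 0.119). The erythroid miR-144, miR-144* and miR-451 had differences of -1.30 ± 0.52, -1.06 ± 0.43 and -0.97 ± 0.47 and did not pass the test over all miRNAs (list median -0.59, camera adjusted p = 0.292). Adjusted over the list alone, 2 of its 6 members were lower and 1 was higher. Without the slide block miR-144, miR-144* and miR-451 passed, with -1.901 (adjusted p = 0.00101), -1.530 (0.00421) and -1.505 (0.00406). The list then had a median of -0.93 (camera adjusted p = 0.0594). For the miR-181 family the median was -0.21 (camera adjusted p = 0.412) and 0 of 4 members passed the test in limma or had an unadjusted p under 0.05 (adjusted p 0.516 to 0.963).

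In total 67 of 390 miRNAs were called between ET and RT, 58 higher and 9 lower in ET (86.6% higher), with 111 at an unadjusted p under 0.05. The split was 17 higher and 18 lower with the percentile over all probes, 30 and 19 with quantile normalization, 36 and 27 with RMA, 32 and 25 in the deposited table and 1 and 2 with normexp, and the median of all differences shifted by -0.16, -0.15 and -0.11 with the percentile over all probes, normexp and the deposited table. Without slide 4, 7 or 10 the count was 13, 24 or 15.

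**Figure D3:**
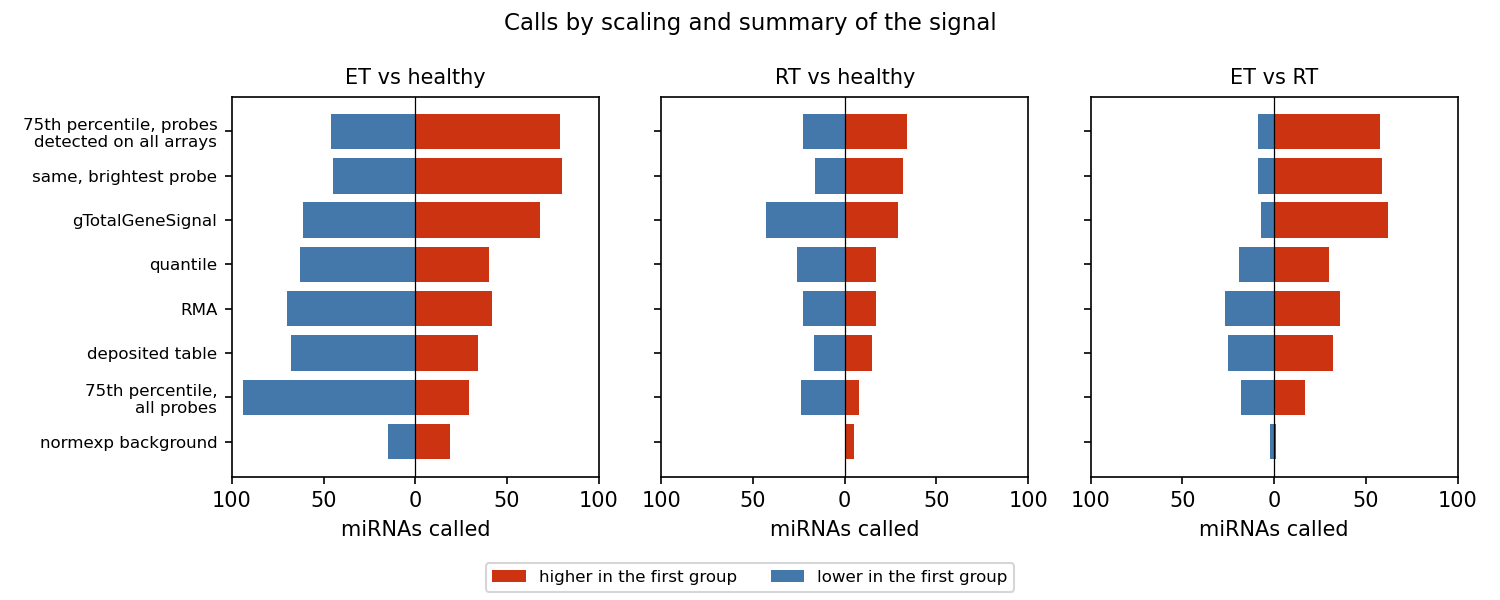
Number of miRNAs called lower (left, blue) and higher (right, red) in the first group of each comparison under 8 scalings and summaries of the signal. ET against healthy gives 79 higher and 46 lower in the top bar, and 29 and 94 when the percentile is taken over all probes.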

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

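The tests of slides for the 3 patterns weighed here and of scaling and dim arrays for the DLK1-DIO3 list were chosen after the results were seen, as were the adjustments for array brightness.

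Regrouping the arrays within slides 100 times, the real grouping included, gave as many calls as the real groups 1 time for ET against healthy (125, highest other 33), 1 time for RT against healthy (57, highest other 4) and 1 time for ET against RT (67, highest other 3). A share of 1 in 100 is the smallest that these regroupings can give. It argues against chance for these counts and does not exclude it. The 40 shared calls were also reached 1 time (highest other 0), but 0 of the 99 other regroupings had calls in both comparisons with healthy. Any shared count above 0 would thus have ranked first. For the 40 this test cannot decide on chance, nor on whether ET and RT share changes beyond the calls themselves. Regroupings of all 3 groups gave at most 67, 25 and 59 calls in the 3 comparisons, the last of these near the real 67. For the number of list shifts chance cannot be excluded: 94 of 100 regroupings gave at least 3, with a highest other of 17, several times the real count. Random regrouping sets no group difference, so the list test at the preset correlation of 0.01 passed lists without one. The estimated correlations reached 0.75, and 0 lists passed with them. Within 1 group, the arrays on its single-group slide against the others gave 0 calls in healthy (limma, 19 at an unadjusted p under 0.05) and 0 in RT (limma, 16 at an unadjusted p under 0.05). All 100 regroupings gave as many in both, which a count of 0 makes certain, with a highest other of 4 and 44. In ET there were 6, and 3 of 100 regroupings gave as many. This share is under 0.05 by itself, but it is not adjusted over the 3 groups, so chance is not firmly excluded. The other regroupings gave a median of 0 and at most 89, so a single regrouping can give many calls. An effect of the slide on the ET arrays was neither shown nor excluded by this test.

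miR-34a, miR-34b*, miR-9, miR-9*, miR-490-3p and miR-490-5p had a median log2 difference of 2.62 between ET and healthy. Array brightness as a covariate left it at 2.59, with a median SE of 0.26, which argues against brightness as the whole cause. The mean of the 6 was higher in ET on 8 of 8 slides, by 1.07 to 3.02, which argues against the slide. The scaling and summary of the signal stay open for the size, since the median was 0.795 under RMA and 0.832 under normexp, which both start from signals corrected by normexp with an offset of 50. The part of the offset in this was not tested. The direction held in 7 of 7 scalings, and a change in the platelets of ET remains a hypothesis. Signal shared between the probes for miR-34a and miR-34b* was not tested, so these may not be separate changes.

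The DLK1-DIO3 list stood out because ET and RT differed in their effects against healthy, by a median of 1.28 in the direct test. It was 1.28 with array brightness as a covariate, which argues against brightness as the whole cause. 0 of the 4 dim arrays were ET or RT arrays on a slide shared by both, and among the 19 ET and 14 RT arrays there the median was 1.33 (SE of the mean over members 0.41), which argues against dim arrays as the source. The mean of the members was higher in ET on 6 of 7 slides (-0.05 to 2.38), and without slide 4, 7 or 10 the median was 1.11, 1.27 or 1.18, which argues against a single slide as the source of the direction, but 0, 6 or 1 of the 44 members then passed in limma (37, 41 and 41 at an unadjusted p under 0.05). The scaling and summary of the signal stay open for the size, since the smallest median was 0.440, under normexp, with 0.499 under RMA. With an estimated correlation the list did not pass (adjusted p = 0.575), and differences between the ET and RT samples other than the disease stay open and were not tested.

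The probe for hiv1-miR-H1, which the comparisons of human miRNAs did not use, was well above background on 24 of 49 patient arrays and 2 of 30 healthy arrays. This is a probe signal and says nothing about any infection. On mixed slides the counts were 16 of 34 and 2 of 22 (permutation p = 0.00197, adjusted over 3 probes 0.00591), which argues against the slide. The log2 difference in signal between patients and healthy was 0.186 without brightness and 0.204 ± 0.157 (SE) with brightness beside the slide. The signal itself thus differed little, and the contrast rests on counts past the background mark. An effect of brightness cannot be told apart at this spread. Its signal followed human miRNAs (highest r over the arrays 0.857 after the group and slide were removed, with miR-1181, a name chosen after its values were seen), so that signal shared with human RNA may be the source.

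miR-490-3p also differed in its effects, by a fitted 2.34 in the direct test, a size that depends on the floor. Of the 67 miRNAs called between ET and RT, 32 were past the threshold in exactly 1 of the comparisons with healthy, 34 in neither and 1 in both. 49 had opposite signs in those comparisons, 31 of them in the DLK1-DIO3 list, whose members vary together. Choosing miRNAs by their difference between ET and RT favours opposite signs. 0 miRNAs were called in opposite directions against healthy.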

How the results depend on the processing

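Array brightness as a covariate and the removal of dim arrays were chosen after the results were seen, and the other alternatives were planned. The cause of a moved count was not tested unless stated.

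For ET against healthy the 125 calls became 69 on mixed slides without a block, 34 with normexp, 63 among miRNAs well above background on all arrays, which are fewer by construction, and 69 at an adjusted p under 0.01. Leaving out slides gave at least 79 (without slide 9). Without the dim arrays, mostly healthy ones, 123 were called, and 93 of the 125 stayed called.

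For RT against healthy the 57 calls became 96 without a slide block, 28 on mixed slides without a block, 37 with the row and column of the array, 32 with the percentile over all probes, 32 in the deposited table, 23 without the filter on dim miRNAs, 28 among miRNAs on all arrays, 119 with array weights, 18 at an adjusted p under 0.01 and 88 with brightness as a covariate. With normexp there were 5: miR-142-3p, miR-148a, miR-338-3p, miR-363 and miR-424. Leaving out slides gave at least 19 (without slide 7), and 31, 30, 29, 20 and 21 without slides 3, 5, 8, 9 and 11. Without the dim arrays 41 were called, 31 higher and 10 lower, and 31 of the 57 stayed called. The decreases in RT thus rested in part on a few dim healthy arrays.

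For ET against RT the 67 calls became 102 without a slide block, 38 on mixed slides without a block, 20 with the row and column, 35 with the percentile over all probes, 21 without the filter, 29 among miRNAs on all arrays, 105 with array weights and 9 at an adjusted p under 0.01. With normexp there were 3: miR-34a, miR-125a-5p and let-7e. Leaving out slides gave at least 13 (without slide 4), and 24 and 15 without slides 7 and 10.

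The 40 shared calls became 15 on mixed slides without a block, 21 with the percentile over all probes, 22 with quantile normalization, 21 with RMA, 4 with normexp (miR-142-3p, miR-148a, miR-363 and miR-424), 15 in the deposited table, 17 without the filter, 20 among miRNAs on all arrays, 82 with array weights, 12 at an adjusted p under 0.01 and 61 with brightness as a covariate. Leaving out slides gave at least 12 (without slide 7), and 22, 23, 23, 13 and 13 without slides 3, 5, 8, 9 and 11. Without the dim arrays 29 were shared, 22 higher and 7 lower.

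The numbers in the sample titles as a replicate block gave 62 calls for ET against healthy, 0 for RT against healthy (limma, 28 at an unadjusted p under 0.05), 10 for ET against RT, 0 shared (limma, 19 at an unadjusted p under 0.05) and 8 list shifts. The deviations of samples with the same number had median correlations of -0.18, -0.03 and -0.08 in the 3 comparisons, over 0.1 in 8 of 27, 8 of 22 and 6 of 22 pairs, and 0, 1 and 0 samples matched best with their own number, so these values give no sign of pairs and the block takes up degrees of freedom.

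The 3 list shifts became 7 without a slide block, 7 with a random block, 5 with the percentile over all probes, 7 with RMA, 13 with normexp, 7 in the deposited table, 12 without the filter, 7 with brightness, 6 without dim arrays and 0 with an estimated correlation. With fry 18 tests passed, 2 of the 3 among them. It tests a list against no change and not against the other miRNAs, so its count answers another question. The miR-181 family in ET had a median of -0.83 among miRNAs on all arrays (adjusted p = 0.169) and did not pass with an estimated correlation (-0.83, 0.575). The DLK1-DIO3 list did not pass with it in RT (-0.65, 0.575) or between ET and RT (1.28, 0.575), nor with fry in RT (0.178).

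The difference in miRNAs well above background between ET and healthy was 22.1 over all arrays (permutation p = 0.0212). Among miRNAs on all arrays, 1 differed between the single-group slide and the other ET arrays. miR-429 turned from 0.31 to -0.00342, -0.0110 and -0.0823 under the percentile over all probes, quantile normalization and normexp. Over 258 named values and their alternatives, 3040 of 3510 checks gave the same outcome, 388 were weaker, 79 stronger and 3 reversed; values past the threshold in neither setting counted as the same even where the sign differed.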

Other observations

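The test over the arms of hairpins and the miRNAs named for the single-group slide were chosen after the results were seen.

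3 miRNAs of 1 transcript, miR-99b, let-7e and miR-125a-5p, were each lower in ET than in RT on 7 of 7 slides, with log2 differences of -0.92, -1.16 and -1.24. miR-99b was not called without the slide block (-0.51, adjusted p = 0.167). Between ET and healthy, miR-449a, which has the seed of miR-34a and was chosen after its values were seen, was 0.51 ± 0.09 (SE) higher in ET. Probes for related sequences can share signal, which was not tested.

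A hypothesis is that the amount of the hairpin sets both arms, since arms of 1 hairpin tended to move alike. Over 99 pairs of arms the log2 differences between ET and healthy had r = 0.741 and rho = 0.692 (permutation p = 1e-05 for both, the smallest the resamples can give; adjusted over 3 comparisons 1e-05), and r = 0.638 without the 2 pairs farthest from the median. In 15 pairs both arms were called, all in the same direction, in 35 only 1 arm was called, and 74 of 99 had the same sign. Between RT and healthy r was 0.544, with both arms called in 3 pairs and 1 arm in 24. Between ET and RT r was 0.831, with both called in 14 pairs and 1 arm in 11. Many of the pairs with large differences there were hairpins of the DLK1-DIO3 list, whose members vary together. This r therefore does not separate the hairpin from the cluster. The correlation is across miRNAs, which are not independent replicates. It may also reflect trends shared by many miRNAs, which this test does not separate.

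The arrays of the single-group ET slide differed from the other ET arrays in 6 miRNAs (limma; random parts of the ET arrays gave up to 89): miR-191 was higher by 0.45, and miR-144, miR-545, miR-219-5p, miR-324-5p and miR-1537 had differences of -2.09, -1.62, -1.30, -0.78 and -0.54. Viral probes for ebv-miR-BART12 and kshv-miR-K12-3 were well above background on all 79 arrays, healthy ones included.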
